A study of Mus musculus with 9 samples.

How the data were processed

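Adult mouse monocytes were incubated for 4 h with a control buffer, adult platelets or P7 platelets and washed before RNA was taken, with 3 libraries per group and 9 in all. RNA was extracted with Trizol, treated with DNase (600 ng per sample), and 100 ng went into oligo-dT selection and stranded mRNA libraries (TruSeq), which were read as 75 nt single ends on a NextSeq sequencer. The values deposited by the authors are raw counts of reads for each of 55367 gene symbols in each library, not normalised. The submitters' processing notes name fastp 0.20.1, STAR 2.7.6a, Subread 2.0.1 with featureCounts, and Salmon 1.3.0, without a role or an order. The genome build, the annotation and the strand setting are not given in the sources used here. Of the symbols, 53292 match gene names of GENCODE M21 and 2075 do not, and positions in the text come from that annotation. Genes with near-identical copies, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, class I MHC genes, and pseudogenes such as Gad1-ps, can share reads, so their separate levels are uncertain.

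Total counts per library ranged from 29687341 to 37065564. Fold changes were estimated with edgeR 4.0.16 in R 4.3.3 from a quasi-likelihood fit to all 9 libraries with 1 mean per group, TMM normalisation and the filterByExpr filter by group (minimum count 10), which left 13707 genes and 6 residual degrees of freedom. The common dispersion was 0.0130, a biological coefficient of variation of 0.114. TMM factors ranged from 0.882 to 1.10. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. The 3 comparisons were adult platelets with control, P7 platelets with control, and P7 with adult platelets. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 35 lists of a comparison, each with at least 5 measured genes. A list's counts of higher and lower genes are given over all genes tested and adjusted over the list alone.

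The lists, the tests, the settings to be varied and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, up to 8 higher and 8 lower called genes with the largest log2 fold change, a mean log2 CPM of at least 2, groups that do not overlap and a symbol that is not a predicted or clone name. It adds up to 4 members of each described list by smallest p, and 14 genes named whatever their values. Genes that moved in opposite directions with adult and P7 platelets, and the genes of 6 further lists, were chosen after their values were seen. Shares of counts were the summed counts of 13 platelet, 5 erythroid or 37 mitochondrially encoded genes in percent of the library total, compared by exact two-sided permutation tests, for which 3 against 3 cannot give a p below 0.1. The mitochondrial rRNA share was added after the data were seen. A fold against a group without counts is a lower bound with a floor of 3 counts over the group's 3 libraries. With 1 to 3 counts in the lower group the ratio is given with a 95% interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

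Overlap between the responses to both kinds of platelets was compared with 20 simulations of unchanged groups against the same control libraries. Alternatives were DESeq2 size factors and upper-quartile factors, no filter and a stricter filter (a mean of 50 counts), the DESeq2 1.42.0 Wald test, limma-voom, glmTreat against a fold of 1.2, a replicate block, only the 2 groups compared, removal of platelet, erythroid and mitochondrial transcripts, an estimated correlation and fry for lists, an adjusted p below 0.01 for the overlap, another denominator for shares, and leaving out each library in turn. A term for the libraries with high Igkc counts, and fits to only those or only the other libraries, were chosen after seeing the data. The method was tested on simulated data with changed genes planted: 70, 71 and 68% of genes changed 1.5-fold and 97, 89 and 93% of genes changed 2-fold were called in the right direction in the 3 comparisons. Unchanged genes made up 7.32, 5.67 and 2.65% of calls, and 0 of 50 unshifted lists were called in each. Genes were simulated independently of one another, so that 0 does not bear on false calls of lists whose genes are correlated. No library was left out of the comparisons.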

Results

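Gene expression was measured by mRNA sequencing in monocytes, the circulating precursors of many tissue macrophages, taken from adult mice and kept for 4 h with a buffer (control), with adult platelets or with P7 platelets. P7 is the usual abbreviation of postnatal day 7 in mice. Platelets are cell fragments without a nucleus that derive from megakaryocytes, carry RNA and bind to monocytes. The monocytes were washed before RNA was taken. Each of the 3 groups holds 3 libraries. Total counts per library ranged from 35314701 to 37065564 for control, from 30974956 to 34394579 for adult platelets and from 29687341 to 35333463 for P7 platelets. In all, 13707 genes had enough counts to be tested. Levels below are normalised CPM, the counts scaled to a common library size, as means ± SD over n = 3 libraries, and log2 fold changes are given ± SE with adjusted p from edgeR's quasi-likelihood test. The labels do not tell whether replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which can be technical. On the first principal component, which held 62.5% of the variance, the control libraries lay at 61.0 to 65.1, the adult platelet libraries at -4.38 to 0.458 and the P7 platelet libraries at -64.3 to -58.3.

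Libraries of monocytes that had been with platelets held more transcripts of platelet genes than control libraries. The summed counts of 13 platelet transcripts made up 0.00264% ± 0.000167 of control libraries, 0.0815% ± 0.0215 with adult platelets and 0.110% ± 0.00862 with P7 platelets (SD, n = 3 each). Globin and Alas2 transcripts, which mark red blood cells and their precursors, made up 0.00105% ± 0.000149, 0.0973% ± 0.0718 and 4.92% ± 0.574 in the same order. The erythroid share was thus 50.6 times as high with P7 as with adult platelets. Without adult platelet replicate 1 the mean erythroid share with adult platelets was 0.0561%. Both mitochondrial rRNAs together rose from 0.148% ± 0.0149 in control to 0.961% ± 0.0939 and 1.03% ± 0.161. All mitochondrially encoded transcripts held 1.47% ± 0.255, 2.14% ± 0.123 and 2.38% ± 0.0449. The platelet, erythroid and total mitochondrial shares of each pair of groups did not overlap (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows). The mitochondrial rRNA shares of the adult and P7 platelet libraries overlapped (exact permutation p = 0.7). Between adult and P7 platelets the platelet share depended on single abundant transcripts. Itga2b averaged 163 and 422 normalised CPM, while Ppbp averaged 224 and 57.5. Of the 13 transcripts, 11 were called higher with P7 platelets and 1, Ppbp, lower. The share is therefore no plain measure of the amount of platelet RNA. Apart from the groups, Igkc, an immunoglobulin light chain transcript of plasma cells and B cells, stood at 410 to 772 CPM of the unscaled library total in control replicate 1, adult platelet replicates 1 and 3 and P7 platelet replicate 1, and at 123 to 172 in the other 5 libraries.

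**Figure D1:**
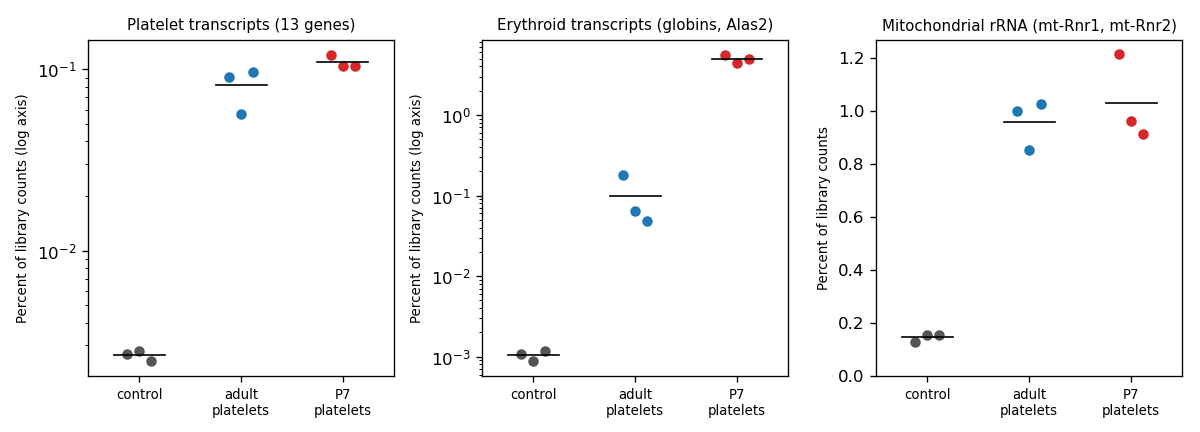
Percent of each library's counts from 13 platelet transcripts, from erythroid transcripts (both on log axes) and from the mitochondrial rRNAs (linear axis), with 1 point per library and a line at the mean of 3. The erythroid share averaged 4.92% with P7 platelets and 0.0973% with adult platelets, while the platelet shares averaged 0.110% and 0.0815%.

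The comparison of adult platelets with control asks what changed in monocyte libraries after contact with platelets of adult mice. Of the gene lists, platelet transcripts had the largest median rise, lists of cholesterol synthesis and of alternative activation and repair were called higher, and the interferon-stimulated list was not called. With an estimated correlation these 3 higher lists were not called (adjusted p = 0.333, 0.686 and 0.209). Arg1, which encodes arginase 1, an enzyme of alternatively activated macrophages, rose from 0.265 ± 0.129 to 7.84 ± 2.33 CPM (log2 fold change 4.87 ± 0.37, adjusted p = 3.85e-05). Stab1, a scavenger receptor gene, rose from 12.6 ± 1.69 to 131 ± 21.5 CPM (3.37 ± 0.25, adjusted p = 3.26e-05). Csf1, which encodes the macrophage growth factor M-CSF, had the largest fall of the named genes, from 83.7 ± 21.9 to 17.2 ± 2.42 CPM (-2.28 ± 0.27, adjusted p = 0.000455). In all, 3617 of 13707 genes changed, 1966 higher and 1651 lower. With upper-quartile scaling the balance turned, with 1620 higher and 1945 lower. At least 2-fold changes were called for 493 higher and 143 lower genes. Of those 493, 271 (55.0%) had a control mean under 0.5 CPM. CPM values of the 2 groups did not overlap for 5856 genes (42.7%, against 10% by chance).

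Of 25 measured platelet and megakaryocyte transcripts, 23 rose and none fell (23 adjusted over the list alone; median log2 fold change 7.82, the same with genes lacking control counts at their bound, camera adjusted p = 4.65e-18). With an estimated correlation, the list had an adjusted p = 0.333. Pf4, the chemokine platelet factor 4, rose from 0.349 ± 0.112 to 138 ± 35 CPM (8.62 ± 0.32), and Ppbp, the precursor of platelet basic protein, from 0.169 ± 0.113 to 224 ± 33.0 (10.33 ± 0.29). On the reference annotation GENCODE M21 (GRCm38), Pf4 lies on chromosome 5 at 90772435 to 90773383 and Ppbp beside it at 90768518 to 90770063. Mpig6b, a receptor of megakaryocytes and platelets, had no count in any control library and was at least 1126-fold higher. Gp6, the platelet collagen receptor, was at least 557-fold higher and Draxin at least 384-fold higher. These bounds take a floor of 3 counts over the 3 control libraries. Alox12, the platelet 12-lipoxygenase gene, was 5129.8 times as high (95% counting interval 1419.7 to 42365). The other named risers were Nrgn (12.49 ± 0.48), Myl9 (11.21 ± 0.43) and Gng11 (10.40 ± 0.38), and Gp9, with few control counts, was 1693 times as high (interval 579 to 8214). Among 15 erythroid transcripts 10 rose (14 adjusted over the list alone; median 2.14, adjusted p = 6.51e-05, and adjusted p = 0.385 with an estimated correlation), among them Hba-a1 (6.39 ± 0.48) and Hbb-bs (6.82 ± 0.55), whose near-identical copies make the split of reads between them uncertain.

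Genes of sterol supply rose together. Of 21 cholesterol synthesis and uptake genes, 15 rose and none fell (15 adjusted over the list alone; median 0.63, adjusted p = 2.17e-07), and the list had an adjusted p = 0.686 with an estimated correlation. Hmgcs1, a synthase gene early in the pathway, rose from 113 ± 14.3 to 219 ± 38.8 CPM (0.95 ± 0.13, adjusted p = 0.00103), and Cyp51, the lanosterol demethylase gene, by 1.10 ± 0.13. Among 17 genes of alternative activation and repair, 7 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0101, with an estimated correlation adjusted p = 0.209). Beside Arg1 these included the growth factor genes Pdgfa (2.38 ± 0.20) and Igf1 (2.13 ± 0.27) and the matrix protease gene Mmp14 (1.77 ± 0.28). The libraries also held platelet RNA, and whether these transcripts came from monocytes or platelets was not tested. In the TGF-beta/SMAD list 9 of 19 genes rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0208, with an estimated correlation adjusted p = 0.686). Pmepa1, a feedback inhibitor of the pathway, rose by 1.96 ± 0.20, the signal transducer gene Smad3 by 0.63 ± 0.10, and Tgfb1 itself by 0.40 ± 0.06. That list's call was lost without adult platelet replicate 3 (adjusted p = 0.1). Whether the rises of Tgfb1, Pmepa1 and Smad3 came from monocytes or from platelet RNA was not tested either.

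Of 22 monocyte migration and adhesion receptors, 7 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0101, with an estimated correlation adjusted p = 0.209). C5ar1, a complement receptor gene, rose from 143 ± 19.3 to 205 ± 12.9 CPM (0.52 ± 0.10), and the integrin beta 2 gene Itgb2 rose by 0.39 ± 0.05. Itga4, the integrin alpha 4 gene, went from 892 ± 103 to 401 ± 127 CPM (-1.15 ± 0.23, adjusted p = 0.00643). Cx3cr1, the fractalkine receptor, rose by 0.51 ± 0.10 (adjusted p = 0.00652). Ccr2 (0.26 ± 0.12, adjusted p = 0.150) and Ly6c2 (0.18 ± 0.12, adjusted p = 0.304), markers of classical monocytes, did not pass the test. Ccr2 passed it without P7 platelet replicate 1 (adjusted p = 0.0441) and Ly6c2 without adult platelet replicate 3 (adjusted p = 0.0144).

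Inflammatory genes rose to a limited extent. Among 23 inflammatory cytokines and chemokines 8 rose and none fell (9 adjusted over the list alone; adjusted p = 0.0208, with an estimated correlation adjusted p = 0.851), and 3 of 19 NF-kB subunits and feedback targets rose (3 adjusted over the list alone; adjusted p = 0.0231, with an estimated correlation adjusted p = 0.851). Without adult platelet replicate 2 neither list was called (adjusted p = 0.150 and adjusted p = 0.352), and without control replicate 2 the NF-kB list was not (adjusted p = 0.0507). Cxcl16 rose from 100.4 ± 9.68 to 247 ± 50 CPM (1.3 ± 0.13). Tnf rose from 45.8 ± 6.70 to 87.2 ± 31.5 CPM (0.93 ± 0.25, adjusted p = 0.0258) and Ccl2 from 0.424 ± 0.0684 to 1.42 ± 0.791 (1.73 ± 0.41, adjusted p = 0.0141). The Tnf call was lost in 4 of 9 fits that each left out 1 library (adult platelet replicates 1 and 2, control replicates 2 and 3; adjusted p = 0.0509 to 0.0975), and the Ccl2 call without control replicate 2 or 3 (adjusted p = 0.0528 to 0.0587). Il1b (-0.23 ± 0.17), Il6 (0.12 ± 0.30), Cxcl2 (0.04 ± 0.17) and Cxcl10 (0.59 ± 0.36) did not pass, with adjusted p = 0.344, 0.805, 0.880 and 0.270.

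Interferon-stimulated genes went both ways. Of 31 measured, 2 rose and 3 fell (2 and 2 adjusted over the list alone; median -0.05, adjusted p = 0.616). Ifit2 rose by 1.56 ± 0.20 and Isg20 by 1.27 ± 0.19, while Cmpk2 (-0.95 ± 0.20, adjusted p = 0.00914) and Zbp1 (-0.67 ± 0.16, adjusted p = 0.0150) fell. The Zbp1 call was lost without control replicate 3 (adjusted p = 0.0529). Immediate-early genes also split, 6 up and 5 down of 24 (6 and 5 adjusted over the list alone; adjusted p = 0.616), with Jun higher (1.53 ± 0.12) and Nr4a1 (-0.79 ± 0.19) and Nr4a2 (-1.55 ± 0.29) lower. The Nr4a1 call was lost without adult platelet replicate 1 or control replicate 3 (adjusted p = 0.0551 to 0.0633). Besides Csf1 and Nr4a2, the named falls were Frmd4b (-2.18 ± 0.23), Map1a (-1.90 ± 0.39), Atp8b1 (-1.71 ± 0.33), Kctd12b (-1.65 ± 0.16), Rnf150 (-1.63 ± 0.25) and the chemokine gene Ccl24 (-1.66 ± 0.46). The Ccl24 call was lost in 5 of 9 fits that left out 1 library (each adult platelet replicate, control replicates 2 and 3; adjusted p = 0.0515 to 0.0954) and in limma-voom (adjusted p = 0.0802).

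Smaller shifts were called for 4 further lists. Of 22 cell cycle genes 12 rose (median 0.22, adjusted p = 6.51e-05, with an estimated correlation adjusted p = 0.330), of 24 nuclear-encoded respiratory chain subunits 9 rose (median 0.17, adjusted p = 0.000125, with an estimated correlation adjusted p = 0.686), and of 16 unfolded protein response genes 5 rose (median 0.20, adjusted p = 0.0101, with an estimated correlation adjusted p = 0.209). Adjusted over the list alone the counts were 12, 11 and 6. Rrm1 (0.33 ± 0.05), Cox5a (0.56 ± 0.07) and Asns (0.88 ± 0.06), which encodes asparagine synthetase, were examples. Among 84 ribosomal protein genes 3 rose (2 adjusted over the list alone; median 0.05, adjusted p = 0.0266, with an estimated correlation adjusted p = 0.851), and that call was lost without adult platelet replicate 1 (adjusted p = 0.967), without control replicate 3 (adjusted p = 0.196) and with a term for the libraries with high Igkc counts, added after the data were seen (adjusted p = 0.186). The remaining 23 lists were not called. Of these, tissue macrophage markers passed without adult platelet replicate 1 (adjusted p = 0.0496) or control replicate 3 (adjusted p = 0.0187) and with the Igkc term (adjusted p = 0.0219), and the haem, iron and NRF2 list without adult platelet replicate 3 (adjusted p = 0.00989) or control replicate 3 (adjusted p = 0.0187) and with that term (adjusted p = 0.0185). Among them, tissue macrophage markers had 5 of 12 genes up and 1 down (adjusted p = 0.0821), with C1qb at 1.52 ± 0.16 against Adgre1 at -0.49 ± 0.09. Haem, iron and NRF2 response genes had 5 of 21 up (adjusted p = 0.0764), phagocytic and scavenger receptors 7 up and 2 down of 17 (adjusted p = 0.333), and coagulation and fibrinolysis genes 6 up and 2 down of 13 (adjusted p = 0.103), with the thrombomodulin gene Thbd at -1.31 ± 0.15. Nonclassical monocyte markers moved both ways (2 up, 4 down of 14, adjusted p = 0.333), with Cd9 at 1.13 ± 0.15 and Eno3 at -1.0 ± 0.15. Whether the rise of Cd9 came from monocytes or from platelet RNA in the libraries was not tested. Classical monocyte markers had 1 of 13 up (adjusted p = 0.616), and MHC class I genes 1 of 16 up (adjusted p = 0.696), which was B2m (0.39 ± 0.06). Counts over the list alone were the same for these 7 lists except classical monocyte markers (0). Of the mitochondrially encoded transcripts only mt-Rnr1 (2.52 ± 0.11) and mt-Rnr2 (2.92 ± 0.13) among 13 rose (adjusted p = 0.501).

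Tests of gene lists were competitive (camera with a preset correlation of 0.01). With an estimated correlation none of the 12 lists called here was called (lowest adjusted p = 0.209). The number of changed genes fell to 2031 without control replicate 2 and to 2207 without control replicate 3.

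P7 platelets were compared with control to ask what changed in adult monocytes after contact with platelets of young mice. All 31 measured interferon-stimulated genes and all 23 measured inflammatory cytokines and chemokines rose. Rsad2, which encodes the antiviral protein viperin, rose from 2.78 ± 0.458 to 170.3 ± 30.2 CPM (log2 fold change 5.94 ± 0.19, adjusted p = 2.67e-07), and Cxcl10, the interferon-induced chemokine, from 4.57 ± 1.02 to 229.9 ± 86.8 CPM (5.65 ± 0.36, adjusted p = 2.61e-06). Tnf rose from 45.8 ± 6.70 to 537 ± 113 CPM (3.55 ± 0.27, adjusted p = 7.48e-06) and Il1b from 552 ± 79.4 to 1648 ± 343 (1.58 ± 0.17, adjusted p = 5.16e-05). Ccr2, the receptor for the monocyte-attracting chemokine CCL2, fell from 2379 ± 231 to 1747 ± 309 CPM (-0.45 ± 0.12, adjusted p = 0.0106). In all, 8111 of 13707 genes changed, 4097 higher and 4014 lower, with 1276 at least 2-fold higher and 974 at least 2-fold lower. Of those 1276, 499 (39.1%) had a control mean under 0.5 CPM. CPM values did not overlap between the groups for 9475 genes (69.1%, against 10% by chance).

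For the interferon-stimulated list the median log2 fold change was 2.93 (31 of 31 adjusted over the list alone; adjusted p = 3.80e-15, with an estimated correlation adjusted p = 0.344). Isg15, a ubiquitin-like modifier, rose from 1.78 ± 0.358 to 64.8 ± 9.97 CPM (5.18 ± 0.22), Isg20 by 5.94 ± 0.19 and Ifit2 by 4.15 ± 0.20. Rsad2 lies on chromosome 12 at 26442746 to 26456452 and Isg15 on chromosome 4 at 156199424 to 156200818. Within the inflammatory list (median 3.19, 23 of 23 adjusted over the list alone; adjusted p = 1.01e-08, with an estimated correlation adjusted p = 0.344) the neutrophil chemokine gene Cxcl2 rose by 2.48 ± 0.16, Cxcl16 by 2.30 ± 0.14, Il6 by 1.3 ± 0.29 and Ccl2 by 1.59 ± 0.41. Of 19 NF-kB subunits and feedback targets 18 rose (18 adjusted over the list alone; median 1.56, adjusted p = 1.31e-07, with an estimated correlation adjusted p = 0.405). Nfkbia, the NF-kB inhibitor gene that NF-kB itself induces, rose from 233 ± 15.7 to 689.9 ± 93.6 CPM (1.56 ± 0.15), and Traf1 by 2.33 ± 0.19. Antigen presentation genes of MHC class I rose, 12 of 16 with 1 lower (the same counts adjusted over the list alone; adjusted p = 0.00109, with an estimated correlation adjusted p = 0.429), among them the class I transactivator Nlrc5 (1.38 ± 0.12) and B2m (0.59 ± 0.06). Beside all of these groups the erythroid share of the P7 platelet libraries was 4.92%, against 0.00105% in control.

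Sterol and iron genes rose as well. All 21 cholesterol genes were higher (21 adjusted over the list alone; median 1.45, adjusted p = 1.01e-08, with an estimated correlation adjusted p = 0.405). Hmgcs1 reached 438 ± 20.1 CPM from 113 ± 14.3 (1.95 ± 0.13), and Cyp51 rose by 2.0 ± 0.13. Of 21 haem, iron and NRF2 response genes 18 rose (18 adjusted over the list alone; median 1.25, adjusted p = 5.87e-06, with an estimated correlation adjusted p = 0.325). Fth1, the ferritin heavy chain, rose from 2089.9 ± 341 to 8330.5 ± 542 CPM (1.99 ± 0.15), the haem transporter gene Slc48a1 by 1.21 ± 0.08 and the biliverdin reductase gene Blvrb by 2.31 ± 0.12. Red cell precursors also express several of these genes, and the erythroid list rose in full, 15 of 15 (15 adjusted over the list alone; median 7.59, adjusted p = 1.59e-08, with an estimated correlation adjusted p = 0.325). Hbb-bs, an adult beta globin, went from 4.41 ± 0.832 to 28812 ± 3650.0 CPM (12.67 ± 0.68), Hba-a2 rose by 12.78 ± 0.67 and Alas2 by 12.37 ± 0.77. The erythroid genes Fech and Mkrn1 were already at 42.1 and 144 CPM in control monocytes. Platelet transcripts rose in 22 of 25 cases (22 adjusted over the list alone; median 8.5, the same with genes lacking control counts at their bound, adjusted p = 1.67e-09, with an estimated correlation adjusted p = 0.385). Mpig6b was at least 2481-fold and Gp6 at least 806-fold higher than in control, where neither had a count. Alox12 was 8449 times as high (counting interval 2339 to 69777), Myl9 rose by 12.60 ± 0.42 and Nrgn by 12.43 ± 0.48. Pf4 reached 172 ± 29.1 CPM and Ppbp 57.5 ± 10.2 CPM.

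**Figure D2:**
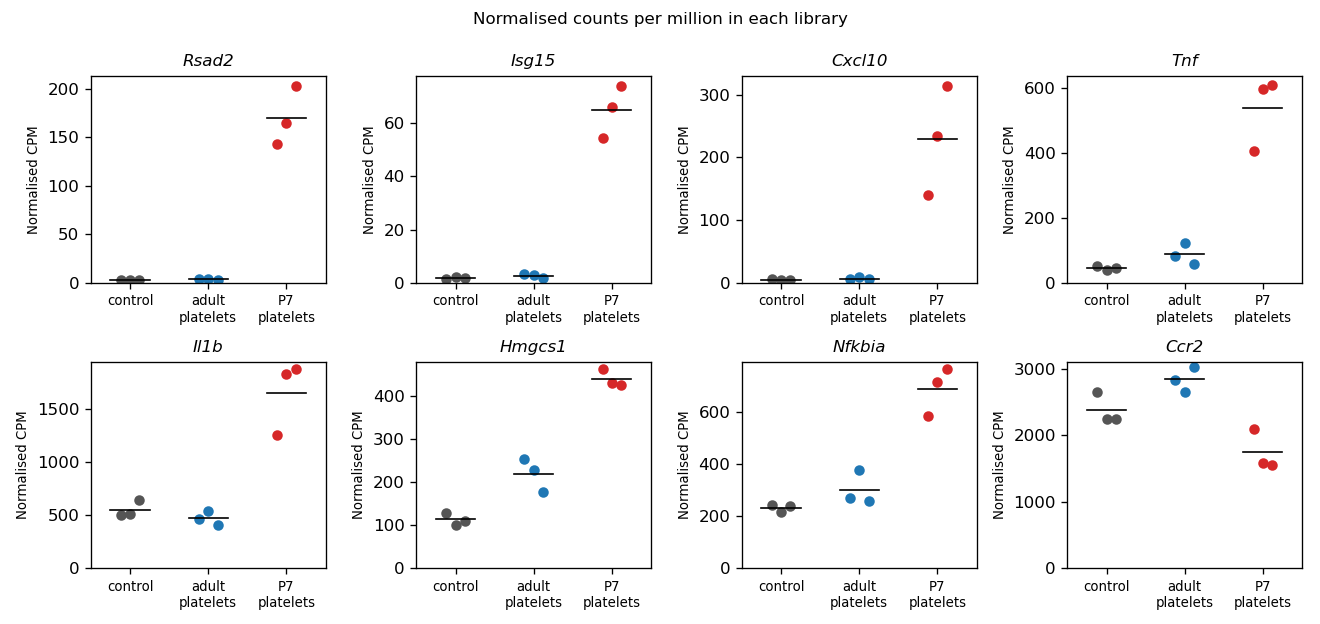
Normalised CPM (linear axes from 0) of 8 genes in each of the 9 libraries, with 1 point per library and a line at the mean of 3. Rsad2, Isg15, Cxcl10, Tnf, Il1b and Nfkbia were higher in every P7 platelet library than in any control or adult platelet library, Hmgcs1 stepped up from control to adult to P7 platelets, and Ccr2 averaged 1747 CPM with P7 platelets against 2379 in control.

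Macrophage markers and stress genes moved with P7 platelets. Of 12 tissue macrophage markers 10 rose (11 adjusted over the list alone; median 1.45, adjusted p = 0.000402, with an estimated correlation adjusted p = 0.325), including the transcription factor gene Maf (3.0 ± 0.15) and Siglec1 (2.42 ± 0.27), which is also interferon-inducible. Among 19 p53 targets and apoptosis genes 14 rose and 2 fell (the same counts adjusted over the list alone; adjusted p = 0.00109, with an estimated correlation adjusted p = 0.325). The survival gene Bcl2l1 rose by 1.18 ± 0.09 and the p53 inhibitor gene Mdm2 by 0.65 ± 0.05. The P7 platelet libraries also held erythroid and platelet RNA. Which cells the transcripts in this paragraph came from was not tested. Immediate-early genes were 13 up and 3 down of 24 (the same adjusted over the list alone; adjusted p = 0.0173, with an estimated correlation adjusted p = 0.405), with Jun at 1.73 ± 0.12 and Fosl1 at 2.51 ± 0.19. Nr4a1 rose by 0.55 ± 0.19 (adjusted p = 0.0333), a call lost in 4 of 9 fits that left out 1 library (control replicates 1 and 2, P7 platelet replicates 2 and 3; adjusted p = 0.0880 to 0.113) and with upper-quartile scaling (adjusted p = 0.0632). The unfolded protein response list had 10 of 16 up and 1 down (adjusted p = 0.00573, with an estimated correlation adjusted p = 0.325), with the chaperone gene Hspa5 at 1.08 ± 0.08. Heat-shock genes had 7 of 12 up and 1 down (adjusted p = 0.0187, with an estimated correlation adjusted p = 0.325), with Hsp90aa1 at 0.87 ± 0.06. Respiratory chain subunits had 19 of 24 up and 1 down (adjusted p = 0.000588, with an estimated correlation adjusted p = 0.464). Adjusted over the list alone these 3 lists kept the same counts. Mitochondrially encoded transcripts were called with 3 of 13 up, 3 adjusted over the list alone (adjusted p = 0.0187, with an estimated correlation adjusted p = 0.464), namely mt-Rnr1 (2.79 ± 0.11), mt-Rnr2 (3.25 ± 0.14) and mt-Nd6 (1.42 ± 0.33). The cell cycle list had 11 of 22 up and 1 down, 11 and 1 adjusted over the list alone (adjusted p = 0.0396, with an estimated correlation adjusted p = 0.429), and its call was lost without control replicate 3 (adjusted p = 0.0844) or P7 platelet replicate 1 (adjusted p = 0.0636).

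The largest named falls with P7 platelets were Rnf150 (-3.37 ± 0.28), Scel (-3.23 ± 0.15), the lipid transporter gene Abca6 (-3.22 ± 0.17), Plekha6 (-3.09 ± 0.17) and Arhgef18, which went from 102 ± 4.47 to 12.8 ± 1.43 CPM (-3.0 ± 0.16). Ndnf (-2.95 ± 0.27), Ypel2 (-2.94 ± 0.21) and Fbxo32 (-2.88 ± 0.15) followed. In lists that were not called, genes of lipid handling split 8 up and 4 down of 17 (8 and 4 adjusted over the list alone; adjusted p = 0.401), with the apolipoprotein E gene Apoe falling from 2169.6 ± 149 to 822 ± 8.17 CPM (-1.40 ± 0.08) and the cholesterol exporter gene Abcg1 at -1.47 ± 0.14. MHC class II genes split 6 up and 3 down of 12 (6 and 3 adjusted over the list alone; adjusted p = 0.538), with H2-DMa at -0.94 ± 0.10 against Cd40 at 2.29 ± 0.37. Of 24 hypoxia and glycolysis genes 10 were higher and 5 lower (10 and 5 adjusted over the list alone; adjusted p = 0.208), with the glucose transporter gene Slc2a1 at 1.56 ± 0.09. Whether the rise of Slc2a1 came from monocytes or from erythroid or platelet RNA in the libraries was not tested. Coagulation and fibrinolysis genes were 8 up and 3 down of 13 (8 and 4 adjusted over the list alone; adjusted p = 0.242), with Serpinb2 at 3.50 ± 0.37 and Thbd at -2.09 ± 0.15. Ly6c2 rose by 0.39 ± 0.12 (adjusted p = 0.0175), a call lost without control replicate 2 or 3 (adjusted p = 0.0541 to 0.0654) and with upper-quartile scaling (adjusted p = 0.0573). Cx3cr1 rose by 0.95 ± 0.10.

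None of the 16 lists called in this comparison was called with an estimated correlation (lowest adjusted p = 0.325). With upper-quartile scaling, which moved the median of all genes by -0.10, 39.5% of the 8291 changed genes were higher, against 50.5% with TMM.

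The direct comparison of P7 with adult platelets asks whether platelet age made a difference to the monocyte libraries. All 31 interferon-stimulated genes were higher with P7 platelets. Rsad2 stood at 170.3 ± 30.2 against 3.65 ± 0.712 CPM (log2 fold change 5.54 ± 0.18, adjusted p = 1.89e-06), Ifit1 at 98.5 ± 32.1 against 1.91 ± 0.785 (5.68 ± 0.35, adjusted p = 1.17e-05) and Cxcl10 at 229.9 ± 86.8 against 6.85 ± 2.44 (5.06 ± 0.35, adjusted p = 2.12e-05). Tnf was higher by 2.62 ± 0.26 and Il1b by 1.81 ± 0.17, while Ccr2 was at -0.70 ± 0.12 (adjusted p = 0.00185). Of 13707 genes 5424 differed, 2706 higher and 2718 lower with P7 platelets, 755 of them at least 2-fold higher and 392 at least 2-fold lower. CPM values did not overlap for 6717 genes (49.0%, against 10% by chance).

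The median of the interferon-stimulated list was 2.94 (31 of 31 adjusted over the list alone; adjusted p = 3.19e-24, with an estimated correlation adjusted p = 0.231), with Isg15 at 4.62 ± 0.21 and Oas2 at 2.80 ± 0.13. Of 23 inflammatory genes 20 were higher (20 adjusted over the list alone; median 2.44, adjusted p = 8.00e-11, with an estimated correlation adjusted p = 0.316). Cxcl2 differed by 2.44 ± 0.16, Ccl3 by 2.74 ± 0.25 and Il6 by 1.18 ± 0.29, whereas Ccl2 was at -0.15 ± 0.38 (adjusted p = 0.790). Among NF-kB subunits and targets 18 of 19 were higher (19 adjusted over the list alone; adjusted p = 8.02e-10, with an estimated correlation adjusted p = 0.391), including Sod2 (1.96 ± 0.25) and Nfkbiz (1.57 ± 0.19). MHC class I genes were 12 higher and 1 lower of 16 (13 and 1 adjusted over the list alone; adjusted p = 2.76e-05, with an estimated correlation adjusted p = 0.391), with Nlrc5 at 1.27 ± 0.12 and Calr at 0.56 ± 0.08. B2m was at 0.20 ± 0.06 (adjusted p = 0.0332), a call lost in 7 of 9 fits that left out 1 library (all but adult platelet replicate 1 and control replicate 1; adjusted p = 0.0503 to 0.0989) and with upper-quartile scaling (adjusted p = 0.150), no low-count filter (adjusted p = 0.138) or only the 2 groups compared (adjusted p = 0.0765). In the same libraries the erythroid share was 4.92% against 0.0973%.

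Cholesterol genes were higher again, 18 of 21 (19 adjusted over the list alone; median 0.76, adjusted p = 2.0e-08, with an estimated correlation adjusted p = 0.475), with Hmgcs1 at 1.0 ± 0.13 and Insig1, a sterol-sensing regulator gene, at 0.76 ± 0.10. Haem, iron and NRF2 genes were higher in 16 of 21 cases (17 adjusted over the list alone; adjusted p = 2.45e-07, with an estimated correlation adjusted p = 0.231). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, stood at 537 ± 53.9 against 233 ± 39.7 CPM (1.2 ± 0.13). Erythroid transcripts had the largest median of the 35 lists, 14 of 15 higher (14 adjusted over the list alone; median 5.32, adjusted p = 6.71e-13, with an estimated correlation adjusted p = 0.231). Alas2, the erythroid enzyme that starts haem synthesis, stood at 3390.2 ± 647 against 46.1 ± 38.6 CPM (6.20 ± 0.56), and Hbb-bt (6.05 ± 0.55), Prxl2a (6.02 ± 0.31), Bpgm (5.93 ± 0.42), Hba-a2 (5.87 ± 0.49), Hbb-bs (5.86 ± 0.51) and Hba-a1 (5.77 ± 0.44) completed the named risers together with Ifit1.

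Platelet transcripts differed in both directions. Of 25, 16 were higher and 2 lower with P7 platelets (the same adjusted over the list alone; median 0.93, adjusted p = 0.000141, with an estimated correlation adjusted p = 0.608). Ppbp stood at 57.5 ± 10.2 against 224 ± 33.0 CPM (-1.96 ± 0.16, adjusted p = 4.60e-05) and Rgs18 at -1.03 ± 0.13, while Gp9, a subunit of the platelet von Willebrand factor receptor, stood at 135 ± 3.30 against 43.6 ± 15.1 CPM (1.63 ± 0.22, adjusted p = 0.000557) and Treml1 at 1.55 ± 0.22. Pf4 was at 0.31 ± 0.18 (adjusted p = 0.214). It passed the test once the libraries with high Igkc counts had their own term, an alternative added after the data were seen (log2 fold change 0.51, adjusted p = 0.000571).

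**Figure D3:**
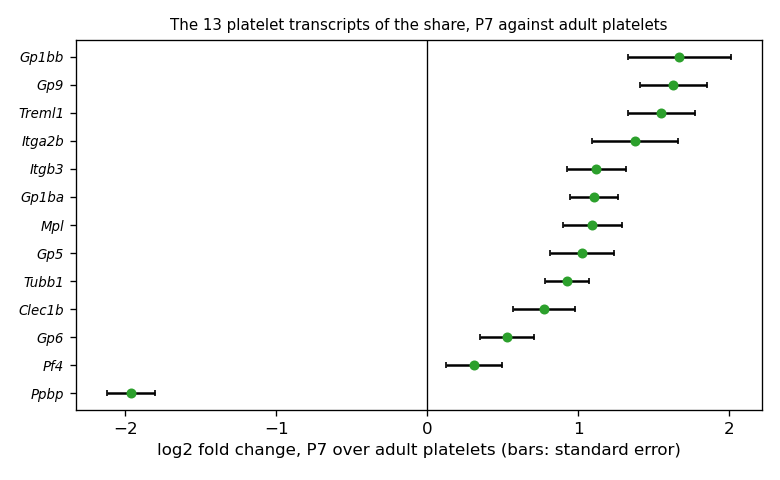
Log2 fold changes (points, with standard errors as bars) of the 13 platelet transcripts of the platelet share, P7 over adult platelets. They range from -1.96 for Ppbp to 1.67 for Gp1bb, with 11 called higher and 1 lower.

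Monocyte and macrophage markers differed too. Of 14 nonclassical monocyte markers 10 were higher (10 adjusted over the list alone; median 0.50, adjusted p = 0.00203, with an estimated correlation adjusted p = 0.529), with Nr4a1 at 1.34 ± 0.20, Adgre4 at 1.74 ± 0.32 and Cx3cr1 at 0.44 ± 0.10. Tissue macrophage markers were 7 higher and 1 lower of 12 (the same adjusted over the list alone; adjusted p = 0.00722, with an estimated correlation adjusted p = 0.391), with Maf at 1.97 ± 0.14 and Adgre1 at 1.06 ± 0.09. Ly6c2 (0.21 ± 0.12, adjusted p = 0.183) and Tgfb1 (0.09 ± 0.06, adjusted p = 0.240) did not pass. Immediate-early genes were 15 higher and 1 lower of 24 (16 and 1 adjusted over the list alone; adjusted p = 0.000592, with an estimated correlation adjusted p = 0.320), among them the phosphatase gene Dusp2 (1.97 ± 0.18). Apoptosis and p53 target genes were 14 higher and 2 lower of 19 (15 and 2 adjusted over the list alone; adjusted p = 8.97e-05, with an estimated correlation adjusted p = 0.231), with Bcl2l1 at 0.95 ± 0.09. Whether the difference of Bcl2l1 came from monocytes or from erythroid or platelet RNA in the libraries was not tested. Heat-shock genes were higher in 6 of 12 cases (adjusted p = 0.00692, with an estimated correlation adjusted p = 0.231) and unfolded protein response genes in 7 of 16 (adjusted p = 0.0227, with an estimated correlation adjusted p = 0.231), with the same counts adjusted over the list alone. The mitochondrially encoded list was called with mt-Nd6 (1.66 ± 0.34) as its only called gene (adjusted p = 0.0116, with an estimated correlation adjusted p = 0.608; 1 gene adjusted over the list alone). Ribosomal protein genes were called lower as a list, 10 of 84 genes and 0 adjusted over the list alone (median -0.10, adjusted p = 0.000617, with an estimated correlation adjusted p = 0.895), and that call was lost without adult platelet replicate 1 (adjusted p = 0.0823).

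The named genes with the largest falls were Tlr5, the flagellin receptor, at 2.56 ± 0.740 against 15.0 ± 4.89 CPM (-2.55 ± 0.27), Arhgef18 (-2.21 ± 0.16), Scel (-2.15 ± 0.15), Abca6 (-2.14 ± 0.17), Fbxo32 (-2.13 ± 0.15), Cgnl1 (-2.12 ± 0.24), Trerf1 (-2.05 ± 0.20) and the pseudogene Gad1-ps (-2.60 ± 0.45), whose reads can be shared with its parent gene. In lists that were not called, the lipoprotein lipase gene Lpl was at 2.96 ± 0.25 and Cpt1a, the gatekeeper of mitochondrial fatty acid oxidation, at -1.03 ± 0.11 (lipid handling, 6 higher and 5 lower of 17, the same adjusted over the list alone, adjusted p = 0.760). Spp1, the osteopontin gene, was at 1.77 ± 0.16 and Trem2 at -0.87 ± 0.10 (alternative activation and repair, 5 and 2 of 17, 5 and 3 adjusted over the list alone, adjusted p = 0.933). Smad7 was at -0.60 ± 0.13 and Tgfbi at -0.75 ± 0.13 (TGF-beta/SMAD response, 2 and 6 of 19, 2 and 7 adjusted over the list alone, adjusted p = 0.468). Migration and adhesion receptors split 8 and 7 of 22 (9 and 7 adjusted over the list alone, adjusted p = 0.891), with the formyl peptide receptor gene Fpr2 at 1.64 ± 0.25 and Selplg at -0.71 ± 0.07.

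The lists for neutrophils, T and NK cells, B and plasma cells, dendritic cells, basophils with mast cells and eosinophils, myeloid progenitors, stromal and endothelial cells and fetal or neonatal transcripts were not called in any comparison. Between P7 and adult platelets the counts of higher and lower genes were 2 and 1 of 16 neutrophil markers (adjusted p = 0.813), 0 and 0 of 6 T and NK cell markers (adjusted p = 0.991), 0 and 0 of 13 B and plasma cell markers (adjusted p = 0.801), 1 and 3 of 13 dendritic cell markers (adjusted p = 0.582), and 0 and 2 of 10 basophil, mast cell and eosinophil markers (adjusted p = 0.541). Myeloid progenitor and granule genes were 2 higher and 7 lower of 13 (adjusted p = 0.114), with Gfi1 at 2.0 ± 0.20 and Cd34 at -1.36 ± 0.19. Stromal and endothelial markers were 2 and 0 of 9 (adjusted p = 0.102), a list that passed in 5 of the 9 fits that left out 1 library (adult platelet replicate 3, each control replicate, P7 platelet replicate 1; adjusted p = 0.0138 to 0.0485). Transcripts typical of fetal and neonatal blood cells were 2 and 0 of 7 (adjusted p = 0.553), with H19 at 1.2 against 0.0208 CPM, 60.4 times as high (95% counting interval 16.3 to 506). Adjusted over the list alone the counts were the same except for the basophil list, where none passed.

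**Figure D4:**
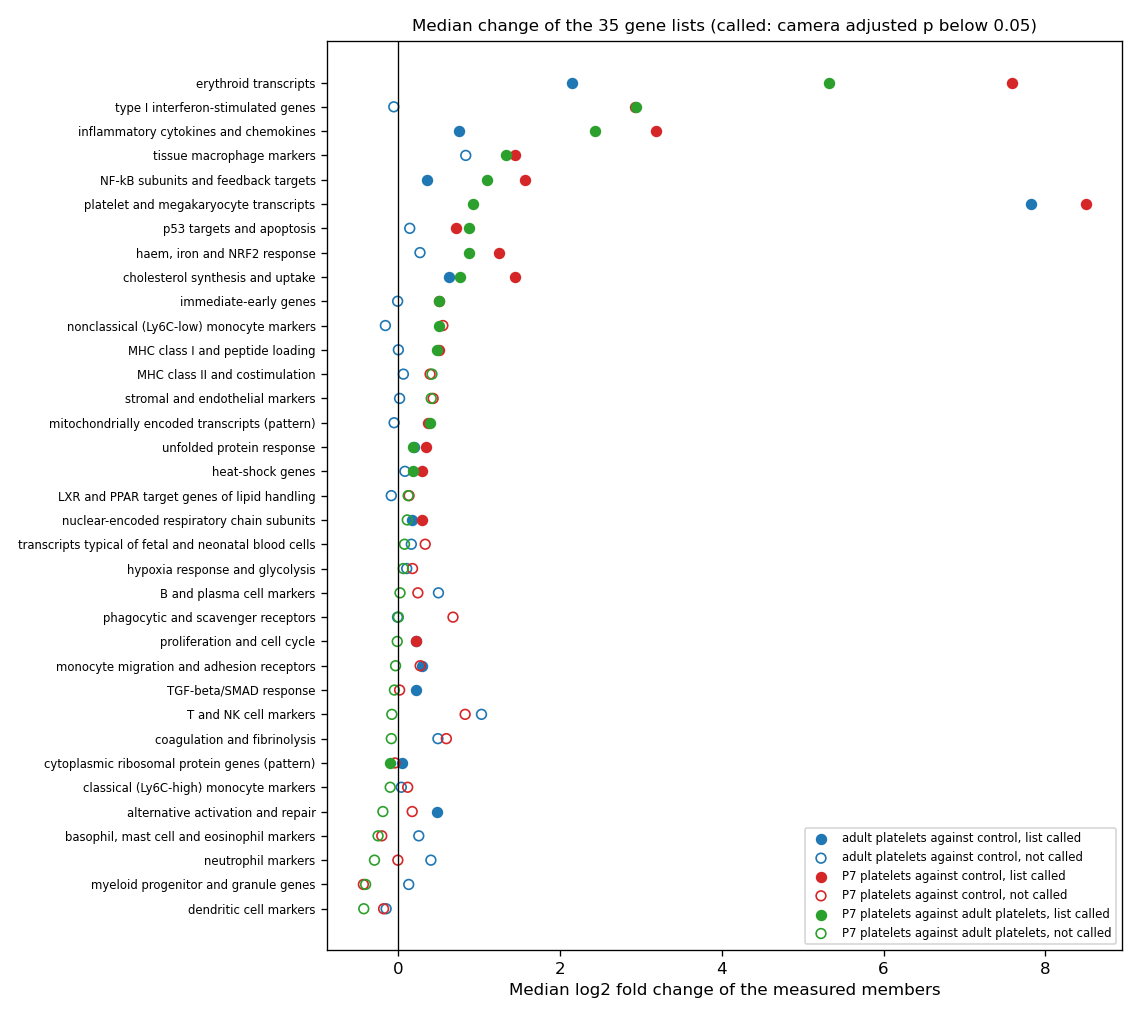
Median log2 fold change (horizontal axis) of the measured members of each of the 35 gene lists in the 3 comparisons, filled where the list was called by camera and open where it was not. Interferon-stimulated genes lie at -0.05 with adult platelets and at 2.93 with P7 platelets.

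None of the 16 lists called between P7 and adult platelets was called with an estimated correlation (lowest adjusted p = 0.231). With upper-quartile scaling 37.2% of the 5662 changed genes were higher, against 49.9% with TMM.

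Whether both kinds of platelets moved the same genes was asked from the overlap of the calls against control. Both comparisons called 3155 genes in the same direction, 1711 higher and 1444 lower, and 65 in opposite directions. Independent lists would share 588 higher and 483 lower genes, and part of the excess over these may come from the shared controls, since 3 control libraries could not be split into 2 sets of at least 2. Unchanged groups simulated against the same control libraries had at most 1 call in a comparison, so they give no expected number of shared calls. Across genes, which are not independent replicates, the fold changes correlated at 0.813, against a mean of 0.510 in 20 simulations of unchanged groups (highest 0.567). Their covariance was 0.863, against 0.0565 simulated, a difference of 0.806. The direction was shared by 79.5% of genes, against 65.9% simulated. The correlation, covariance and shared calls include platelet and erythroid transcripts, whose lists rose in both comparisons and which can come from the platelet preparations. None of these values was computed without such transcripts. How much of the overlap is a shared response of the monocytes themselves was therefore not tested. Without control replicate 2 the shared calls fell to 1832 and without control replicate 3 to 1978. Of the 65 genes with opposite calls, all were also called in the direct test of P7 against adult platelets. These 65 could hardly fail it, since their direct difference in the same fit is larger than either change against control. They comprised 36 lower with adult and higher with P7 platelets, such as Cmpk2 (-0.95 and 1.83) and Adgre1 (-0.49 and 0.57), and 29 the other way, such as Cgnl1 (1.29 and -0.83), whose P7 platelet call was lost without P7 platelet replicate 2 or 3 (adjusted p = 0.0527 to 0.0543).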

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

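All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries. Genes called in opposite directions with adult and with P7 platelets, against the same controls, were singled out. Their calls in the direct test come from the same fit and were all but fixed by that choice. The adjusted p-values of the direct test below are therefore no further support. Zbp1, a sensor of viral nucleic acid, had log2 fold changes of -0.67 with adult and 1.98 with P7 platelets, a difference of 2.65 (adjusted p = 1.11e-05). For Ccl24 they were -1.66 and 1.78, a difference of 3.44 (adjusted p = 0.000594). For Cmpk2 they were -0.95 and 1.83, a difference of 2.79 (adjusted p = 2.79e-05). For Nr4a1 they were -0.79 and 0.55, a difference of 1.34 (adjusted p = 0.000808). For Adgre1 they were -0.49 and 0.57, a difference of 1.06 (adjusted p = 7.26e-05). For Cgnl1 they were 1.29 and -0.83, a difference of -2.12 (adjusted p = 0.000241). Calls against control that 1 left-out library ended are the adult platelet calls of Zbp1 (adjusted p = 0.0529 without control replicate 3), Ccl24 (0.0515 to 0.0954 without any adult platelet replicate or control replicate 2 or 3) and Nr4a1 (0.0551 to 0.0633 without adult platelet replicate 1 or control replicate 3), and the P7 platelet calls of Nr4a1 (0.0880 to 0.113 without control replicate 1 or 2 or P7 platelet replicate 2 or 3) and Cgnl1 (0.0527 to 0.0543 without P7 platelet replicate 2 or 3).

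The first pattern weighed is the rise of interferon-stimulated genes with P7 over adult platelets. A scaling shift from erythroid and platelet RNA moves all genes alike, so it cannot by itself set this list apart from other genes. The list's median was 2.94 and that of all genes -0.02, both with those transcripts kept and with them removed. Their removal moved almost nothing and is no test of such a shift. The difference between libraries with high and low Igkc counts is argued against by a median of 2.84 with a term for it, fitted to all 9 libraries. RNA of lymphocytes or neutrophils is argued against as well, since the highest median of their 3 lists was 0.0235 (SD of members 0.45). Those 3 lists do not cover carried monocytes or macrophages, which were not tested as a source and stay open. Tissue macrophage markers were higher with P7 than with adult platelets (median 1.33, 7 higher and 1 lower of 12). Erythroid cells carried with the P7 platelets could be the source of the signal instead of the platelets and cannot be told apart from them, because the lowest erythroid share with P7 platelets was 24.2 times the highest with adult platelets. The age of the platelet donors also stays open and was not tested apart from this.

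The second pattern is the rise of both mitochondrial rRNAs with platelets of either age. A general rise of mitochondrial transcripts is argued against by the protein-coding ones, whose median with adult platelets was -0.0623 (7 genes, the largest at -0.01) against 2.72 for the rRNAs. With P7 platelets it is argued against by a median of 0.323 (SD of members 0.42) against 3.02, although mt-Nd6 rose by 1.42, the only one of the 7 called, and the next largest change was 0.37. Mitochondrial RNA carried by platelets was not settled. The excess of mitochondrial rRNA per excess of platelet transcripts was 10.7 ± 2.01 with adult and 8.22 ± 0.830 with P7 platelets (SD, n = 3), a ratio of 0.770. Anything else that came with platelets of both ages could give a like ratio. The protein-coding medians of -0.0623 and 0.323 show no matching rise. Carried mitochondrial RNA would therefore have to be mostly rRNA, which was not tested. Weaker poly(A) selection stays open, since other transcripts without a poly(A) tail had a median of 0.67 with adult platelets (6 of 17 called higher, 1 lower, SD of members 1.29) and of 1.12 with P7 platelets (8 called higher, 3 lower, SD 1.81). The rise of 1 that weaker selection was taken to need lies within 2 standard errors of both medians. No biological explanation within the monocytes was tested.

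The third pattern is that platelet transcripts differed from one another between P7 and adult platelets. A different amount of platelet RNA alone is argued against, since the log2 fold changes of the 13 transcripts, from -1.96 to 1.67, spanned 18.3 median standard errors, with 11 called higher and 1 lower. The lower one was Ppbp, and without it the other 12 spanned 6.78. Those 12 all changed upward (lowest 0.31), and the largest change was that of Gp1bb, at only 0.160 and 0.515 CPM with adult and P7 platelets. The argument therefore rests mainly on Ppbp. Expression of the same genes by monocytes stays open: 10 of the 12 called transcripts were at or below 1 CPM in every control library, which does not bear on expression started after contact with platelets. The age of the platelet donors and the carried erythroid cells stay open too, untested.

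The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. Every split but the real one also mixes both groups, which puts any difference between them into the spread within groups. Counts of 0 in those splits are therefore no support. In 1 split, the real one, 3617 genes were called for adult platelets and control, 8111 for P7 platelets and control and 5424 for P7 and adult platelets, and the highest count among the other splits was 0 each time.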

How the results depend on the processing

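The only alternatives chosen after seeing the data are those that use the libraries' Igkc counts. Over 22 settings, 309 pairs of a named gene and a comparison gave 6746 values, of which 0 called values reversed and 18 uncalled ones changed sign. The counts of changed genes below are for adult platelets and control, P7 platelets and control, and P7 and adult platelets. Tested against a fold of 1.2, a stricter question by construction, the counts were 1120, 5185 and 2552. With only the libraries with high Igkc counts (2 adult platelet, 1 control and 1 P7 platelet library, where lone samples are assumed to vary like the other group) they were 308, 1780 and 839, from fewer samples. Other settings stayed within 1.5 times the reported counts: DESeq2's Wald test gave 3744, 7910 and 5259, limma-voom 3746, 8111 and 5356, DESeq2 size factors 3619, 8122 and 5413, upper-quartile factors 3565, 8291 and 5662, no filter 3223, 7930 and 4921, the stricter filter 3453, 7173 and 5067, removed transcripts 3592, 8064 and 5393, only the 2 groups compared 2999, 8532 and 4484, the Igkc term 4213, 8692 and 5579, and only the libraries with low Igkc counts (1 adult platelet, 2 control and 2 P7 platelet libraries, with the same assumption for the lone adult one) 5249, 9345 and 5906. Leaving out 1 library gave 2031 (without control replicate 2) to 3774 (without P7 platelet replicate 1) for adult platelets and control, 7101 to 8482 for P7 platelets and control and 3978 to 5540 for P7 and adult platelets. The shared calls ranged from 1832 (without control replicate 2) to 3108 (without adult platelet replicate 3) and were 1553 at an adjusted p below 0.01. The cause of the drop without control replicate 2 or 3 was not tested. Those 2 libraries were unusually alike, with a chi-square of their counts per degree of freedom of 4.67, against 18.1 and 24.4 for the other control pairs. P7 platelet replicates 2 and 3 were too (5.58, against 25.8 and 29.4). How far the counts of calls rest on these 2 close pairs was not tested. With an estimated inter-gene correlation 0, 0 and 0 lists were called, and with fry, which does not compare a list with other genes, 12, 24 and 18. With a denominator without mitochondrial, platelet and erythroid transcripts, which is smaller by construction, the P7 platelet library shares were 0.119% for platelet and 2.58% for mitochondrial transcripts. Of the 294 called gene results, calls ended for 25 against a fold of 1.2, 85 with the high-Igkc libraries, 3 with upper-quartile factors, and 1 each with limma-voom, no filter, only the 2 groups compared and the low-Igkc libraries. Of 15 uncalled ones, 7 were called with the low-Igkc libraries (Cxcl10, Ly6c2, Ccr2, Cd14 and C3 for adult platelets and control, Pf4 and Tgfb1 for P7 and adult platelets), all resting on that lone adult platelet library, adult platelet replicate 2, against 2, and so not read as support for a change. With the Igkc term, which keeps all libraries, 1 was called (Pf4). Over the 9 fits that each left out 1 library, 31 of 2646 gene calls ended and 2 of 135 uncalled gene results were called, and 9 of 396 list calls ended and 11 of 549 uncalled list results were called. Median and mean differed in sign for 5, 1 and 4 of the 35 lists, as did median and camera direction, none of them called. Depth limits low levels most: fits rest on genes with a count of about 10 or more.

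With a replicate block (paired by the replicate number) the counts were 4228, 8565 and 5965 and the called lists 12, 16 and 16. The block ended or added no call of the named genes and lists. The numbers were not taken to pair the samples, since the labels do not say that a number marks a shared culture or animal. The values do not exclude pairing. After removing group means 7 of 9 same-numbered pairs correlated above 0.1 (all 9 from -0.081 to 0.576). Both others involve adult platelet replicate 3, and the 3 pairs of control and P7 platelet libraries correlated at 0.209 to 0.576. Of the 9 libraries 5 matched best with their own number. Pairs from different groups on the same side of the Igkc difference correlated at 0.0529 or more, and pairs across it at 0.00609 or less.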

Other observations

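The gene lists in this part were put together after the data were seen, and their results are descriptions. Of 20 ribosome biogenesis genes, 8 rose and 0 fell with adult platelets, and 12 rose and 2 fell with P7 platelets (camera adjusted p = 0.00496 and 0.00190, with an estimated correlation 0.147 and 0.297). Nop58, a nucleolar protein gene, averaged 35.4, 58.1 and 83.6 CPM in control, adult and P7 platelet libraries. Of 19 amino acid transporters and tRNA synthetases, 10 rose with adult platelets and 14 rose and 2 fell with P7 platelets (adjusted p = 0.00174 and 0.00149, with an estimated correlation 0.675 and 0.486), with Gars at 169, 218 and 273 CPM. Of 14 complement genes, 8 rose and 1 fell with adult platelets, and 8 rose and 2 fell with P7 platelets (adjusted p = 0.000715 and 0.0400, with an estimated correlation 0.147 and 0.297). C3, the central complement component, averaged 959, 1084 and 1902 CPM, and its receptor gene C3ar1 66.6, 153 and 139. The change of C3 with adult platelets was not called (quasi-likelihood test, adjusted p = 0.301). Cd59a, nearly absent from control, averaged 0.0250, 1.70 and 7.86 CPM. Whether its rise came from monocytes or from platelet or erythroid RNA in the libraries was not tested.

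Lysosomal and Toll-like receptor genes moved in both directions. Of 24 lysosomal genes, 4 rose and 4 fell with adult platelets, and 4 rose and 14 fell with P7 platelets (adjusted p = 0.421 and 0.0678). Man2b1, a lysosomal mannosidase gene, averaged 411, 335 and 266 CPM, while the protease gene Ctsb averaged 739.6, 918 and 1433. Of 20 Toll-like receptors and adaptors, 8 were higher and 5 lower with P7 than with adult platelets (adjusted p = 0.635). Tlr2, a receptor for bacterial lipoproteins, averaged 508, 812 and 1121 CPM, Cd14 834, 753 and 1653, and Tlr8, a receptor for single-stranded RNA, 170.5, 127 and 99.1. The difference of Tlr2 between P7 and adult platelets was not called without P7 platelet replicate 2 or 3 (adjusted p = 0.0514 and 0.0520).

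Xist, the transcript of the inactive X chromosome, stood at 0.539 to 0.635 CPM of the library total in the P7 platelet libraries, with 1 count in adult platelet replicate 3 and 0 in the other 5 libraries. Which cells it came from, including any carried with the P7 platelets, was not tested.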
